A study of Mus musculus with 6 samples.

How the data were processed

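RNA from the whole terminal ileum of 6 mice was sequenced, 1 library per mouse, with 3 mice labelled as floxed for Il17ra with Atoh1-driven Cre and 3 as littermates without Cre. Per the labels' protocols, the animals received DSS and were sampled on day 6, and directional libraries were made with the NEBNext Ultra II kit. The submitters' processing notes name FastQC, Trimmomatic, STAR, SAMtools, bedtools, Cufflinks and Cuffnorm and the mouse builds GRCm38 and mm10, without versions or settings. The authors deposited 1 table of FPKM values (fragments per kilobase of transcript, scaled to sequencing depth), with 23402 gene symbols and 1 column per library. FPKM values are not counts, so no count model was fitted. How the libraries were scaled to each other, how fragments that match several genes were shared out and whether strand was used in counting are not given in the sources used here.

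Groups and replicate numbers were taken from the sample labels, and the table's columns were matched to samples by the genotype and number in their names. The libraries correlated with each other between 0.980 and 0.985 (Spearman's rho across genes, which are not independent replicates), with no pair standing out as a duplicate, and 5640 genes were listed at 0 in all 6. Most low values fell in steps of whole fragments, while some alpha-defensin copies were listed far below the value of 1 fragment. Between 70.2% and 74.6% of ratios of low values to those of the library labelled Cre-negative 1 matched ratios of whole numbers up to 6 within 0.02 on the log2 scale, against a median of 8.62% at shifted scales. From these steps, depth relative to that library was between 0.851 and 0.978, and the steps corresponded to 8110000 to 9510000 fragments. These depths are estimates, and the libraries labelled Cre-positive 2 and 3 were the shallowest. Near the filter of 1 FPKM, a gene's value rests on few fragments.

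Symbols were matched to the GENCODE M21 annotation of GRCm38 (21854 symbols) and then to current (211) or older (1213) symbols of the RefSeq gene table, and 124 were not matched. Coordinates are those of GENCODE, and Defa4 was given no position. The 43 gene lists were fixed before the data were examined. Of 979 entries, 30 were found under an older symbol, a step added after the data were seen, and 30 had no match, among them constant-region genes of immunoglobulins and T cell receptors.

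Genes with a mean of at least 1 FPKM over all 6 libraries were tested (12695) on the log2(FPKM + 1) scale. This scale understates the change of genes with low values. The test was limma's moderated test with an intensity trend (two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with at least 3 tested members were compared with limma's camera at a preset correlation between genes of 0.01, adjusted over 43 lists. Members were also adjusted over the list alone. Single values were compared with exact two-sided permutation tests, which cannot go below 0.1 for 3 against 3 animals. The tools were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

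The rule for named genes was also set before the data were examined. It took Il17ra and Atoh1, then up to 12 genes in each direction past the threshold whose groups did not overlap, and filled each direction to 12 with the smallest p values. Predicted or clone-named loci, small RNAs, variable receptor segments and sex-linked genes were left out of that part. The rule then added the 4 members with the smallest p value of each list that passed its test and allowed 2 of each other list. Genes named outside it are said to be so where they appear. A gene that the rule names is not reported here.

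On simulated data with the measured means and spreads of 12695 genes, 200 of them changed, the test recovered 26.6% of genes changed 1.5-fold, 53.7% of those changed 2-fold and 89.4% of those changed 4-fold. Over 5 simulations, 20 of 584 calls were false. A seeded list was called, and so was 1 other list. The simulated genes varied independently of each other. In the deposited data the estimated correlation was 0.80 for B cell genes and 0.91 for proliferation genes. The simulation therefore does not measure how often lists are falsely called there. The median standard error of a log2 fold change in the deposited data was 0.13.

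The alternatives set in advance were pseudocounts of 0.1 and 5, no filter and a filter of 5 FPKM, median-of-ratios scaling, rescaling to an equal sum, quantile normalization, limma without the trend, with robust estimation or with array weights, a minimum fold of 1.5, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. A sex term, the Cre-positive group reduced to its replicate 3, exact list symbols only and the counts adjusted over the list alone under each setting were added after the data were seen.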

Results

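Gene expression was measured by RNA sequencing of whole terminal ileum, the last segment of the small intestine, from 6 mice aged 6 weeks on day 6 of dextran sodium sulfate (DSS) in the drinking water. DSS is a polysaccharide that injures the intestinal epithelium and is used to model colitis. All animals carried floxed alleles of Il17ra, which encodes a subunit of the receptor for the cytokine interleukin-17 (IL-17). In 3 of them, labelled Cre-positive, the recombinase Cre was driven by Atoh1, the transcription factor gene that specifies the secretory lineage of Paneth, goblet and enteroendocrine cells. The other 3, labelled Cre-negative, were littermates without Cre. The comparison between the groups asks what the loss of IL-17 receptor signalling in secretory cells does to the ileal transcriptome during DSS exposure. No animals without DSS were analysed here, so an effect of DSS itself could not be measured. Each library listed between 16317 and 16547 genes above 0, and steps in the lowest values corresponded to about 8110000 to 9510000 fragments per library.

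Il17ra itself was not lower in the libraries labelled Cre-positive. Its level was 6.16 ± 0.324 FPKM (SD, n = 3) in the libraries labelled Cre-negative and 7.45 ± 1.22 FPKM (SD, n = 3) in those labelled Cre-positive. The single values were 6.04, 5.91 and 6.53 FPKM against 7.93, 8.36 and 6.07 FPKM. The log2 fold change was 0.23 (SE 0.13, limma adjusted p = 0.998), and an exact two-sided permutation test gave p = 0.2, where 0.1 is the smallest value that 3 against 3 animals allow. The gene lies on chromosome 6 from 120463247 to 120487559 (GRCm38), and its value covers all exons together. Which exons are floxed is not given in the sources used here, and whole tissue holds many cells outside the Atoh1 lineage. The labels were therefore not checked by this gene, and every direction below is that of the libraries as labelled. Atoh1, on chromosome 6 from 64729125 to 64731245, stood at 9.61 ± 1.25 FPKM and 10.4 ± 1.07 FPKM in the libraries labelled Cre-negative and Cre-positive (SD, n = 3 each; log2 fold change 0.10, exact permutation p = 0.5).

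**Figure D1:**
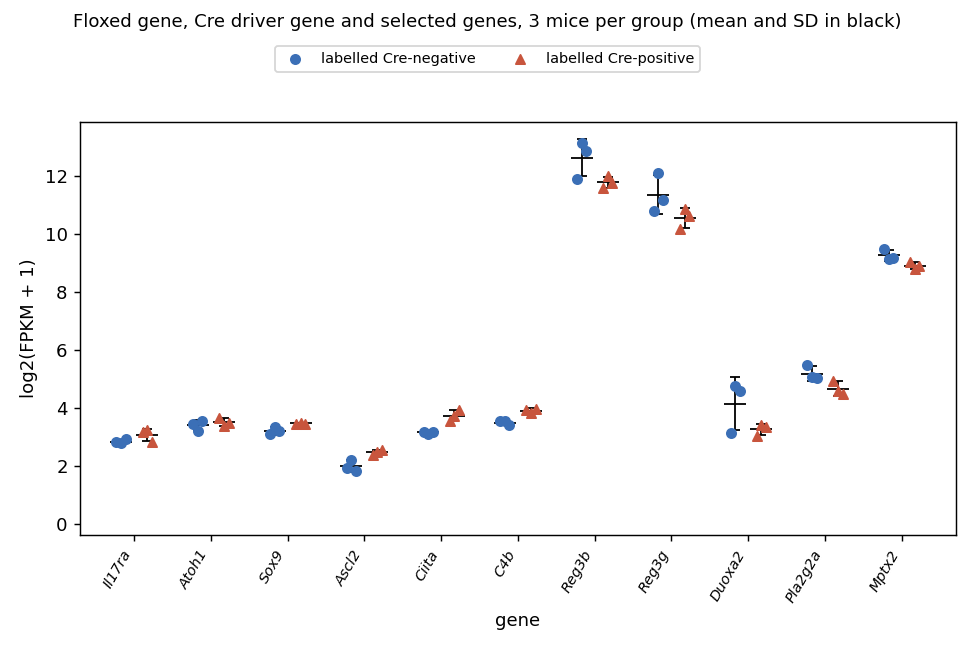
Expression of Il17ra, Atoh1 and 9 other genes on the log2(FPKM + 1) scale (vertical axis) in each library; circles are libraries labelled Cre-negative, triangles those labelled Cre-positive, and black bars the mean and SD of 3 mice. Il17ra was 6.16 FPKM on average in the first group and 7.45 FPKM in the second, with the lowest triangle inside the range of the circles.

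No single gene passed the test between the groups. With limma, 0 of 12695 genes reached an adjusted p of 0.05, and 459 had an unadjusted p under 0.05 (323 higher and 136 lower in the libraries labelled Cre-positive), against 634.75 expected by chance. The balance depended on the scaling, with 1200 higher and 59 lower after rescaling to an equal sum, 288 and 207 with median-of-ratios scaling and 269 and 219 under quantile normalization. It also depended on single libraries, with 182 higher and 231 lower without Cre-negative 3, 449 and 374 without Cre-positive 1, 106 and 81 without Cre-positive 2 and 463 and 103 without Cre-positive 3. The values of 732 genes were higher, and of 330 genes lower, in all 3 libraries labelled Cre-positive than in all 3 labelled Cre-negative, together 8.37% of genes where chance gives 10%. The smallest adjusted p values belonged to 2 alpha-defensin genes, Gm10104 (0.0743) and Defa4 (0.0940). Among genes with the smallest unadjusted p values that were higher in the libraries labelled Cre-positive were Dbp, a clock-controlled transcription factor, Ciita, the master regulator of MHC class II genes, and C4b, a complement component. Ciita stood at 7.94 ± 0.233 FPKM and 12.4 ± 1.74 FPKM (SD, n = 3 each; log2 fold change 0.57), and C4b at 10.3 ± 0.596 FPKM and 14.1 ± 0.732 FPKM (SD, n = 3 each; 0.41). Others on this side were Ocel1 (log2 fold change 0.64), the amino acid oxidase gene Il4i1 (1.16), Nuggc (0.73), the peptide transporter gene Slc15a2 (1.24), Phxr4 (0.66) and Slc5a4a (0.56). On the other side were Tm4sf20 (-0.70), the MHC class II transcription cofactor gene Rfxank (-0.44), Slc25a14 (-0.48), the acid ceramidase gene Asah1 (-0.43), B3gnt3 (-0.53), Mgat4c (-0.72), the fatty acid binding protein gene Fabp4 (-0.53), Atraid (-0.47) and Hsd17b6 (-0.59). None of these passed the threshold. Without the library labelled Cre-positive 3, 46 genes passed it, 45 of them higher, while no more than 2 did when any other library was left out.

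Alpha-defensins, the bactericidal peptides of Paneth cells at the base of the crypts, separated the groups in both directions. Of 25 list members tested, 14 passed the threshold adjusted over the list alone, 4 higher and 10 lower in the libraries labelled Cre-positive, and 0 when adjusted over all genes. Gm10104, whose current symbol is Defa35 (chromosome 8 from 21065038 to 21065996), was listed at 44.6, 17.2 and 41.9 FPKM in the libraries labelled Cre-negative and at 1017, 459 and 621 FPKM in those labelled Cre-positive (log2 fold change 4.33, SE 0.40). Defa4 was listed at about 0 in all 3 libraries labelled Cre-negative and at 68.6, 22.1 and 12.8 FPKM in those labelled Cre-positive. Defa25 averaged 0.333 ± 0.576 FPKM and 3.35 ± 1.87 FPKM, and Defa-rs7 averaged 8.29 ± 5.41 FPKM and 30.0 ± 2.47 FPKM (SD, n = 3 each). In the opposite direction, Defa3 averaged 308 ± 82.5 FPKM and 123 ± 46.5 FPKM, Defa26 328 ± 101 FPKM and 147 ± 50.0 FPKM, and Gm15293 (Defa41) 7.45 ± 1.24 FPKM and 0.738 ± 0.640 FPKM (SD, n = 3 each). Over 26 measured rows of the family, a pseudogene included, 4 were higher and 7 lower in all 3 libraries labelled Cre-positive, where chance gives 1.3 in each direction. These genes are near-identical copies whose reads the authors' quantification had to share out, so the value of any 1 copy is uncertain. The summed FPKM of the family was 42354 ± 10687 in the libraries labelled Cre-negative and 25904 ± 7321 in those labelled Cre-positive (SD, n = 3 each; ratio 0.612, exact two-sided permutation p = 0.2). Adjusted over the list alone, 7 of 12 members passed when only exact current symbols were matched.

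**Figure D2:**
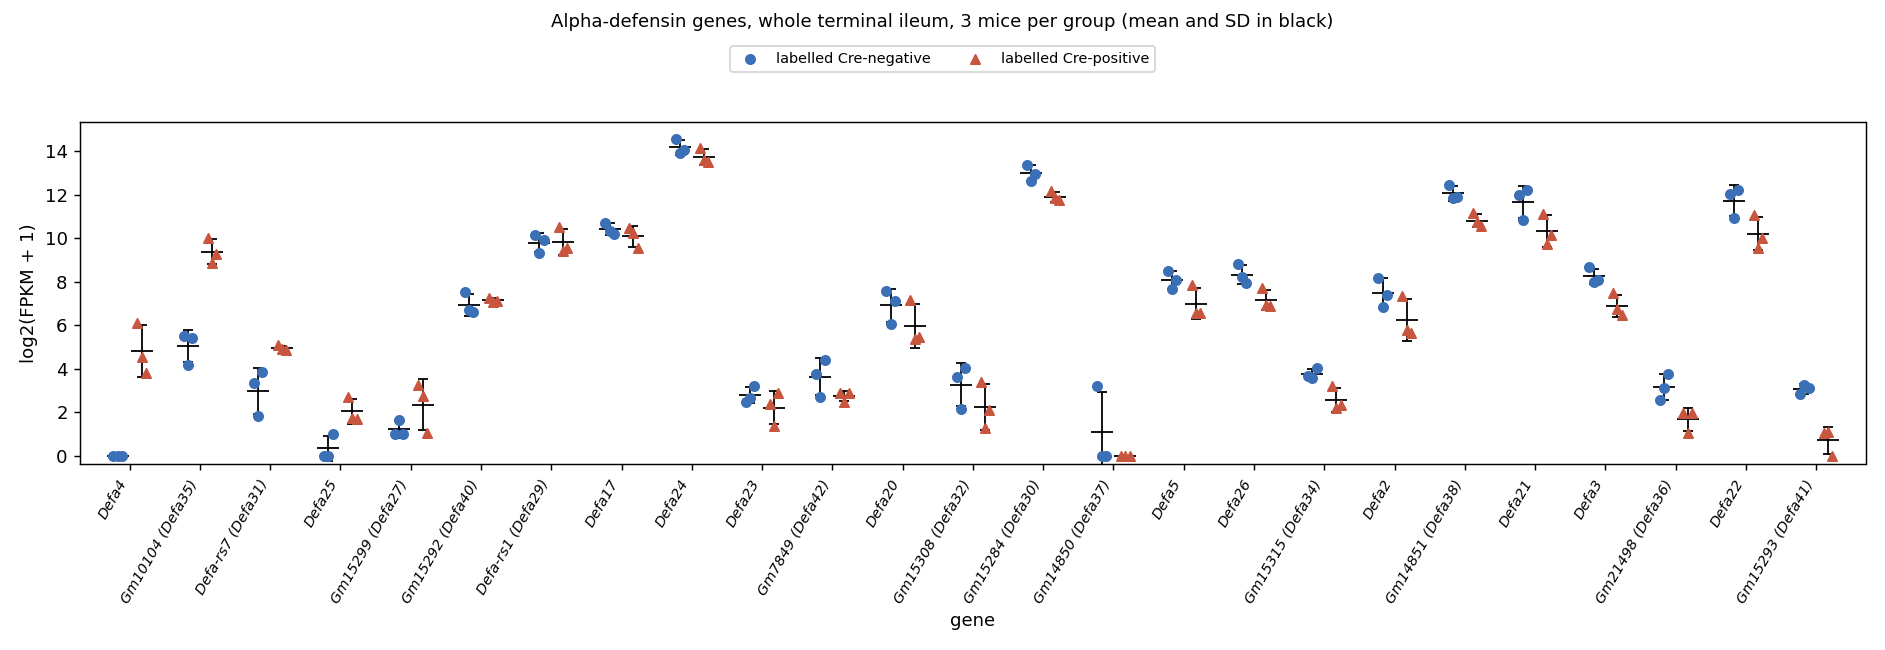
Expression of 25 alpha-defensin genes on the log2(FPKM + 1) scale (vertical axis), ordered by log2 fold change, with current symbols in parentheses; circles are libraries labelled Cre-negative, triangles those labelled Cre-positive, and black bars the mean and SD of 3 mice. Gm10104 lies between 17.2 and 44.6 FPKM in the first group and between 459 and 1017 FPKM in the second, while Defa3 and Gm15293 lie lower in the second group.

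Paneth cell genes, antimicrobial proteins and targets of IL-17 signalling were lower as sets in the libraries labelled Cre-positive by limma's camera test with a preset correlation. These lists share members, so their calls are not separate results. Lyz1, Pla2g2a, Ang4, Itln1 and Mptx2 stand in both the Paneth cell and antimicrobial lists. Reg3b, Reg3g, Lcn2, S100a8 and S100a9 stand in both the antimicrobial and IL-17 target lists. The Paneth cell list also holds several alpha-defensins. The Paneth cell list had 22 of 26 estimates below 0 (median log2 fold change -0.36, adjusted p = 9.69e-10), and its call was lost with the correlation estimated (adjusted p = 0.385 with an estimated correlation). Without the alpha-defensins, a list made after the values were seen, 13 of 15 estimates were below 0 (median -0.28). With an estimated correlation, camera gave this shorter list an unadjusted p = 0.154. Its mean in Cre-positive 1 (0.12) lay inside the range of the libraries labelled Cre-negative (-0.11 to 0.34). The means in Cre-positive 2 (-0.20) and Cre-positive 3 (-0.25) lay below that range. The Paneth cell list held 3 members past the threshold adjusted over the list alone, Defa3 and Defa26 lower and Defa25 higher. The alpha-defensin list was called lower (median -1.03, mean -0.24, adjusted p = 8.96e-07; adjusted p = 0.426 with an estimated correlation), although its members with the smallest p values went both ways. Of the antimicrobial proteins, 13 of 16 estimates were below 0 (median -0.31, adjusted p = 1.03e-05; adjusted p = 0.334 with an estimated correlation), and the median was -0.10 without Cre-negative 1. Pla2g2a, a secreted phospholipase with bactericidal activity, stood at 35.9 ± 6.62 FPKM and 24.7 ± 4.50 FPKM, and Mptx2, a mucosal pentraxin, at 624 ± 82.3 FPKM and 483 ± 40.8 FPKM (SD, n = 3 each). The C-type lectins Reg3b and Reg3g, which IL-17 induces in epithelium, had log2 fold changes of -0.86 (SE 0.37) and -0.81 (SE 0.36). Reg3b averaged 6859 ± 2716 FPKM in the libraries labelled Cre-negative and 3582 ± 484 FPKM in those labelled Cre-positive (SD, n = 3 each), and the ranges overlapped. The IL-17 target list, with 11 of 19 estimates below 0, was called lower (median -0.15, adjusted p = 0.00448; adjusted p = 0.334 with an estimated correlation). Its median was 0.0051 without Cre-negative 2 and -0.08 without Cre-positive 3, and the call was lost under quantile normalization (adjusted p = 0.0607). Duoxa2, the maturation factor of an epithelial hydrogen peroxide generator, had a log2 fold change of -0.89 and S100a9 one of -0.43, and 0 members of this list reached an unadjusted p under 0.05. Goblet cell genes (median -0.04, adjusted p = 0.459), secretory lineage transcription factors (median -0.03, 0.695), tuft cell genes (median 0.05, 0.906) and IL-17 cytokines and receptors (median 0.01, 0.754) were not called. Enteroendocrine genes, among them Sct (-0.41), Sst (-0.24), Pyy (-0.43) and Nts (-0.37), were called lower with a median of -0.09 (adjusted p = 0.0195; adjusted p = 0.334 with an estimated correlation). The enteroendocrine call was lost without the library labelled Cre-negative 3 (adjusted p = 0.0845) or Cre-positive 3 (0.0665) and with array weights (0.0815), and its median was -0.01 without Cre-negative 1.

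B cell genes were many times higher in 2 of the 3 libraries labelled Cre-positive and at the level of the Cre-negative libraries in the remaining one. Ms4a1, which encodes the B cell surface protein CD20, stood at 0.154, 0.264 and 0.111 FPKM in the libraries labelled Cre-negative and at 9.37, 11.3 and 0.302 FPKM in those labelled Cre-positive. Cd37 and Vpreb3 had log2 fold changes of 1.42 and 1.15. All 18 estimates of the list were above 0 (median 1.25, camera adjusted p = 1.73e-12; adjusted p = 0.374 with an estimated correlation). By limma, 0 of its members passed the threshold adjusted over the list alone, and 13 had an unadjusted p under 0.05. The median was 1.88 without Cre-positive 3. With the group reduced to the library labelled Cre-positive 3, an alternative chosen after the values were seen, the list's direction turned (adjusted p = 0.546). MHC class II and antigen presentation genes were called higher (15 of 19 estimates above 0, median 0.24, adjusted p = 9.91e-04; adjusted p = 0.385 with an estimated correlation), with Ciita the only member past the threshold adjusted over the list alone. Nlrc5, the corresponding activator of MHC class I genes, stood at 3.39 ± 0.555 FPKM and 5.62 ± 1.62 FPKM (SD, n = 3 each). The B cell forms H2-Ob (log2 fold change 1.40) and H2-DMb2 (1.11) followed the libraries rich in B cell genes. The antigen presentation call was lost without the library labelled Cre-positive 1 (adjusted p = 0.254) and with array weights (0.257), and its median was 0.41 without Cre-positive 2 and 0.14 without Cre-positive 3. Without H2-Oa, H2-Ob and H2-DMb2, a list made after the values were seen, 12 of 16 estimates were above 0 (median 0.19). With an estimated correlation, camera gave this shorter list an unadjusted p = 0.302. Its mean in Cre-positive 2 (-0.13) lay inside the range of the libraries labelled Cre-negative (-0.17 to 0.01). The means in Cre-positive 1 (0.22) and Cre-positive 3 (0.17) lay above that range. Cxcr5 and Ccr6, in the list of group 3 innate lymphoid and type 17 genes (not called, adjusted p = 0.275), and Clu, in the epithelial repair list (not called, adjusted p = 0.695), were likewise high in the libraries labelled Cre-positive 1 and 2 alone, Clu at 49.1 and 36.7 FPKM against 3.62 FPKM in the third. T cell and NK cell genes (median 0.10, adjusted p = 0.225) and plasma cell genes (median 0.16, 0.0765) were not called.

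**Figure D3:**
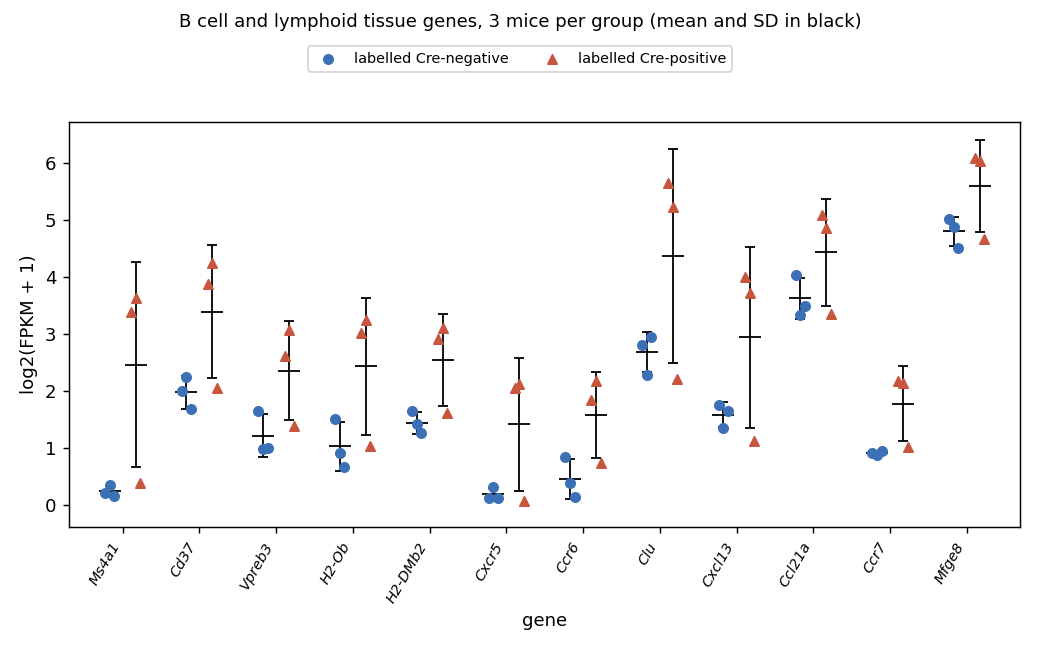
Expression of B cell genes and other genes of lymphoid tissue (Cxcl13, Ccr7 and Mfge8 chosen after their values were seen) on the log2(FPKM + 1) scale (vertical axis); circles are libraries labelled Cre-negative, triangles those labelled Cre-positive, and black bars the mean and SD of 3 mice. Ms4a1 lies at 9.37 and 11.3 FPKM in a pair of triangles and at 0.302 FPKM in the other.

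Clock genes differed between the groups in opposite directions. Of 14 circadian clock genes tested, 5 passed the threshold adjusted over the list alone and 0 when adjusted over all genes. The 5, of which all but Dbp and Nfil3 were chosen after their values were seen, were Dbp, Tef and Per3 (higher in the libraries labelled Cre-positive) and Nfil3 and Arntl (lower). Dbp averaged 4.36 ± 0.831 FPKM and 8.74 ± 0.841 FPKM (log2 fold change 0.87), and Nfil3, a repressor that competes for the same DNA sites, 9.37 ± 0.946 FPKM and 5.87 ± 1.08 FPKM (-0.60; SD, n = 3 each). Tef, a factor of the same family as Dbp, had a log2 fold change of 0.54, the period gene Per3 one of 0.51 and Arntl, which encodes the core activator BMAL1, one of -0.29. The list was not called in 1 direction (camera adjusted p = 0.323). Limma's rotation test fry, run for change in either direction, gave an adjusted p = 0.0928 over 43 lists. The count of 5 fell to 1 without the library labelled Cre-negative 2 or Cre-positive 2, and to 3 without Cre-negative 1, Cre-negative 3 or Cre-positive 3. It was 2 with median-of-ratios or quantile scaling or without a filter, 3 with a pseudocount of 5, 1 with a sex term (chosen after the values were seen), 0 with a minimum fold of 1.5 and 11 with array weights.

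**Figure D4:**
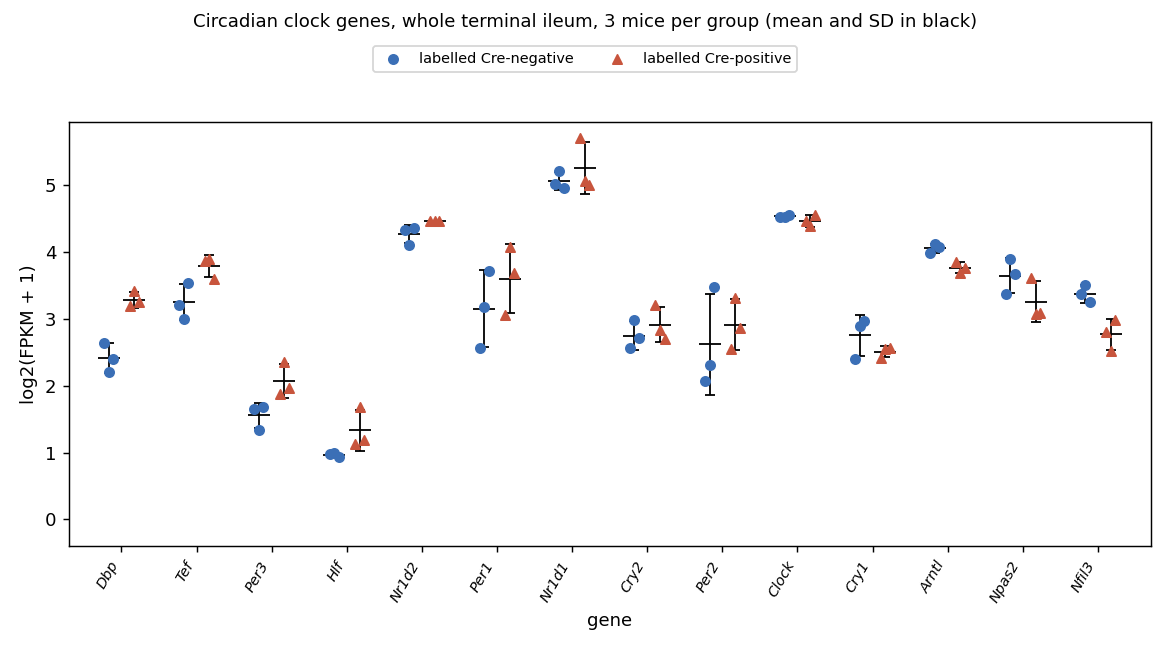
Expression of 14 circadian clock genes on the log2(FPKM + 1) scale (vertical axis); circles are libraries labelled Cre-negative, triangles those labelled Cre-positive, and black bars the mean and SD of 3 mice. Dbp averages 4.36 FPKM in the first group and 8.74 FPKM in the second, and Nfil3 9.37 FPKM and 5.87 FPKM.

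Most Wnt target, Notch pathway and proliferation genes had small positive estimates in the libraries labelled Cre-positive. Wnt targets were called higher (13 of 16 estimates above 0, median 0.20, camera adjusted p = 0.00615; adjusted p = 0.405 with an estimated correlation). The median was 0.12 without Cre-negative 3, and the call was lost with array weights (adjusted p = 0.270). Ascl2, a stem cell transcription factor, averaged 3.00 ± 0.550 FPKM and 4.52 ± 0.342 FPKM (SD, n = 3 each), and Sox9 had a log2 fold change of 0.25, while Cd44 and Rnf43 had log2 fold changes of 0.32 and 0.23. The Notch pathway list, led by Lfng (0.33), Notch2 (0.30), Notch1 (0.28) and Rbpj (0.19), was called higher (median 0.11, adjusted p = 0.0214; adjusted p = 0.614 with an estimated correlation) and lost the call without Cre-negative 1 (adjusted p = 0.163) or Cre-positive 2 (0.453), with a median of 0.17 without Cre-negative 2. It was also lost without a filter (0.177), after rescaling to an equal sum (0.0728), under quantile normalization (0.0627), and, in settings chosen after the values were seen, with a sex term (0.0582) and with the group reduced to Cre-positive 3 (0.471). Proliferation genes, including Mcm2 (0.29), Aurkb (0.30), Mcm4 (0.29) and Rrm2 (0.28), had 25 of 26 estimates above 0 (median 0.13, adjusted p = 0.0381; adjusted p = 0.765 with an estimated correlation). That direction turned without Cre-negative 3 (adjusted p = 0.554) or Cre-positive 3 (0.902), and the call was lost without Cre-positive 2 (0.168), without a filter (0.0782), after rescaling to an equal sum (0.101), with array weights (0.171) and with the sex term (0.0582). The median was 0.27 without Cre-negative 1, 0.20 without Cre-negative 2 and 0.27 without Cre-positive 1. Cholesterol and lipid synthesis was called higher (23 of 27 above 0, median 0.09, adjusted p = 0.0308; adjusted p = 0.735 with an estimated correlation), with the desaturase gene Scd1 at 13.7 ± 2.67 FPKM and 25.5 ± 6.62 FPKM (SD, n = 3 each). Dhcr7 (0.24), Srebf1 (0.19) and Fasn (0.34) followed, and the call was lost without Cre-negative 3 (adjusted p = 0.436) or Cre-positive 3 (0.902), without a filter (0.0556) and with array weights (0.663). Its median was 0.16 without Cre-negative 1, 0.14 without Cre-negative 2 and 0.17 without Cre-positive 1. The intestinal stem cell list was not called (median 0.10, adjusted p = 0.111).

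Xenobiotic metabolism, adipose, interferon, bile acid and absorptive enterocyte lists were called lower in the libraries labelled Cre-positive by camera with the preset correlation. Xenobiotic metabolism had 22 of 29 estimates below 0 (median -0.16, camera adjusted p = 4.40e-07; adjusted p = 0.334 with an estimated correlation), with the carboxylesterase genes Ces1g (-0.61) and Ces2a (-0.42) and the cytochrome genes Cyp2c55 (-0.91) and Cyp2c65 (-0.40). Adipose genes, among them Fabp4, the lipid droplet gene Plin1 (-0.47), Cfd (-1.13) and Retn (-0.76), had 9 of 11 estimates below 0 (median -0.39, adjusted p = 3.00e-06; adjusted p = 0.334 with an estimated correlation). The adipose median was -0.62 without Cre-negative 1 and -0.23 without Cre-negative 3, and the xenobiotic median was -0.27 without Cre-negative 2 and -0.28 without Cre-positive 1. Interferon response genes were called lower (median -0.10, adjusted p = 9.91e-04; adjusted p = 0.541 with an estimated correlation), with Ifit1 (-0.66), Xaf1 (-0.33), Ifih1 (-0.27) and Isg15 (-0.90). The interferon call was lost without Cre-negative 2 (adjusted p = 0.156), and its median was -0.15 without Cre-negative 3. Ileal bile acid handling, with Slc51b (-0.34), Nr1h4 (-0.30), Fgf15 (-0.84) and Amn (-0.21), was called lower (median -0.30, adjusted p = 0.00906; adjusted p = 0.405 with an estimated correlation) but not without Cre-negative 3 (adjusted p = 0.977), in which Fgf15 stood at 7.70 FPKM, nor under quantile normalization (0.0627) or with array weights (0.383). Absorptive enterocyte genes had 21 of 26 estimates below 0 (median -0.12, adjusted p = 0.0182; adjusted p = 0.765 with an estimated correlation), although Slc2a2 (0.26) and Slc2a5 (0.13) lay above 0 while Dpp4 (-0.25) and Mttp (-0.14) lay below. This call was lost without Cre-negative 2 (adjusted p = 0.0538), Cre-positive 2 (0.174) or Cre-positive 3 (0.902), and its direction turned without Cre-negative 3 (0.581) and under quantile normalization (0.807). The median was -0.22 without Cre-negative 1 and -0.29 without Cre-positive 1.

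The remaining calls were lower in the libraries labelled Cre-positive, and each was lost with an estimated correlation. They covered erythroid genes (median -0.31, adjusted p = 0.00615; adjusted p = 0.334 with an estimated correlation), neutrophil genes (-0.18, 0.0182; 0.373) and exocrine pancreas genes (-0.23, 0.0204; 0.334). They also covered smooth muscle (-0.07, 0.0177; 0.674), type 2 immunity (-0.19, 0.0283; 0.346), oxidative phosphorylation (-0.06, 0.0109; 0.765), PPAR targets and fatty acid oxidation (-0.06, 0.0446; 0.373), and immediate early and heat shock genes that mark tissue handling (-0.08, 0.0281; 0.674). Each of these 8 calls was also lost when 1 library was left out. The adjusted p was 0.354 for erythroid genes without Cre-positive 1, 0.207 and 0.0811 for neutrophil genes without Cre-negative 1 or Cre-positive 1, and 0.0855 and 0.0665 for exocrine pancreas genes without Cre-negative 1 or Cre-positive 3. It was 0.318 and 0.173 for smooth muscle without Cre-negative 1 or Cre-positive 2, and 0.0871 for type 2 immunity without Cre-positive 2, whose call was also lost without Cre-negative 3 (median -0.16). For oxidative phosphorylation it was 0.712, 0.0658 and 0.331 without Cre-negative 1, Cre-negative 2 or Cre-positive 1, and for PPAR targets 0.735, 0.185 and 0.352 without Cre-negative 3, Cre-positive 2 or Cre-positive 3. The direction of the handling genes turned without Cre-negative 3 (0.800) or Cre-positive 3 (0.684). Array weights ended the erythroid (0.167), neutrophil (0.0754), exocrine pancreas (0.0815), type 2 (0.0790), PPAR (0.138) and handling (0.868) calls. Quantile normalization ended the exocrine pancreas (0.146), smooth muscle, type 2 (0.0626), PPAR (0.496) and handling (0.149) calls and turned oxidative phosphorylation (0.798). Without a filter the exocrine pancreas (0.101), neutrophil (0.454), type 2 (0.177), PPAR (0.0761) and handling (0.139) calls were lost. A filter of 5 FPKM ended the erythroid (0.0572), exocrine pancreas (0.0532), neutrophil (0.857), PPAR (0.0963) and handling (0.0570) calls, and median-of-ratios scaling the PPAR (0.0581) and handling (0.0906) calls. The sex term ended the smooth muscle (0.116), oxidative phosphorylation (0.0545) and PPAR (0.0575) calls. With the group reduced to Cre-positive 3 the erythroid (0.0996), neutrophil (0.520) and smooth muscle (0.134) calls were lost and oxidative phosphorylation turned (0.893). Medians moved as well. Without Cre-negative 1 they were 0.02 for smooth muscle, 0.05 for oxidative phosphorylation, -0.26 for handling, -0.10 for neutrophil and -0.04 for PPAR genes. Without Cre-negative 2 the oxidative phosphorylation median was -0.04. Without Cre-negative 3 the medians were -0.11 for smooth muscle, -0.17 for oxidative phosphorylation, 0.03 for handling, -0.28 for neutrophil and -0.04 for PPAR genes. Without Cre-positive 1 they were -0.08 for erythroid, 0.00378 for oxidative phosphorylation and -0.17 for handling genes. Without Cre-positive 2 they were -0.63 for erythroid, -0.10 for type 2, -0.14 for handling and -0.03 for PPAR genes, and without Cre-positive 3 they were -0.10 for oxidative phosphorylation, 0.03 for handling and -0.02 for PPAR genes. In all, 24 of 43 lists passed with the preset correlation of 0.01, 6 higher and 18 lower, 0 passed with an estimated correlation (smallest adjusted p = 0.334) and 0 with fry (smallest adjusted p = 0.526). Fry for change in either direction passed 1 list, the alpha-defensins (adjusted p = 3.05e-04). With each of the 6 libraries left out in turn, 8 of the 24 calls held throughout: B cell, Paneth cell, alpha-defensin, antimicrobial, xenobiotic, adipose, IL-17 target and Wnt target genes. These runs kept the preset correlation, under which other splits of the 6 libraries into 3 and 3 gave 11 to 19 calls. Holding therefore does not show an effect of the groups. The lists of colon identity (adjusted p = 0.0724), fibroblasts and matrix (0.297), macrophages (0.323), complement (0.375), endothelium (0.820), eosinophils and mast cells (0.589), enteric neurons and glia (0.163), the unfolded protein response (0.295) and sex-linked genes (0.128) were not called. The median, mean and test differed in sign for the unfolded protein response, epithelial repair, secretory transcription factors and IL-17 cytokines and receptors.

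**Figure D5:**
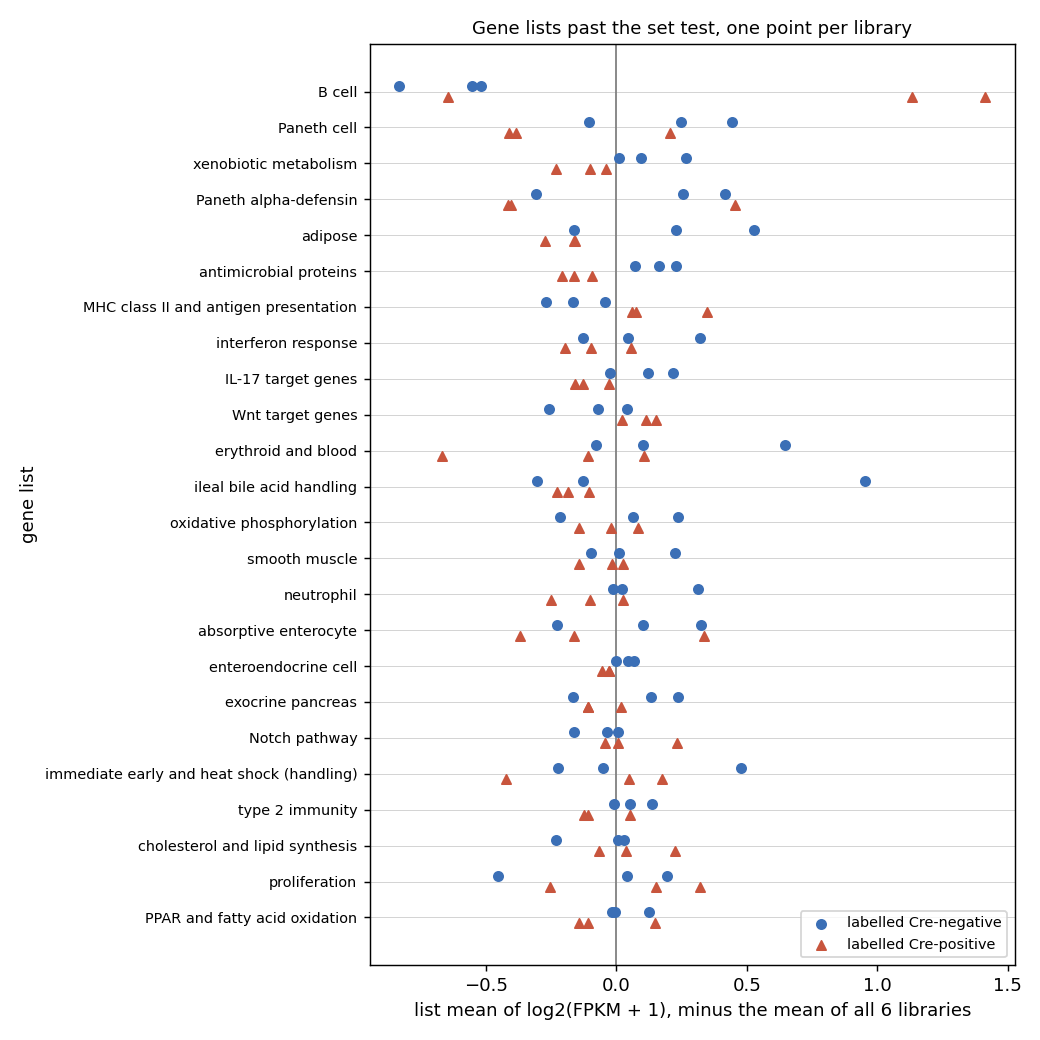
Mean log2(FPKM + 1) over the genes of each list that passed camera with the preset correlation (rows), as the difference from the mean of all 6 libraries (horizontal axis); circles are libraries labelled Cre-negative and triangles those labelled Cre-positive, 1 point per library. B cell genes stand at 1.13 and 1.41 in a pair of triangles and at -0.65 in the other, and most other lists overlap between the groups.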

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

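Tests under a sex term, with the Cre-positive group reduced to replicate 3, with exact list symbols, and of the counts adjusted over the list alone were chosen after the results were seen. Against 0 genes past the threshold, pseudocounts of 0.1 and 5 gave 2 genes each (2 higher; 1 higher and 1 lower), rescaling to an equal sum gave 2 (2 higher) and array weights 24 (11 higher, 13 lower). The Cre-positive group reduced to replicate 3, a lone library assumed to vary like the others, gave 4 (2 higher, 2 lower). No filter, a filter of 5 FPKM, median-of-ratios scaling, quantile normalization, limma without the trend or with robust estimation, the minimum fold of 1.5 and the sex term gave 0, with 770, 269, 495, 488, 476, 461, 21 and 453 genes at an unadjusted p under 0.05 against 459 in the planned test. With array weights 1741 of these were higher and 976 lower, and with a filter of 5 FPKM 160 and 109. Leaving out each library gave 0 to 46 genes, 0 to 45 higher and 0 to 2 lower. The 46 came without Cre-positive 3, against 2 without Cre-negative 1, 2 without Cre-negative 3 and 1 without Cre-positive 1. Rescaling to an equal sum moved the median log2 fold change of all genes from 0.03 to 0.14. The causes were not tested.

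The labels do not say whether the replicate numbers pair littermates. The deviations of same-numbered libraries correlated at -0.13, 0.03 and -0.11 across genes, which shows no pairing but cannot exclude one. With the replicate block, 1 gene passed (Gm10104, higher), 25 lists passed, the proliferation call was lost (adjusted p = 0.0564), and 1 clock gene and 19 alpha-defensins passed over the list alone.

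The 24 lists became 14 with array weights and 0 with an estimated correlation or fry, and between 16 and 26 in the other settings, 19 to 24 with a library left out. Robust estimation and the minimum fold have no counterpart in camera. Of the 24 calls, 5 held in all 18 settings that keep the preset test (adipose, antimicrobial, Paneth cell, alpha-defensin and xenobiotic genes). The Paneth cell list shares members with the antimicrobial and alpha-defensin lists, so those calls are not separate. Directions turned under quantile normalization for absorptive enterocyte (adjusted p = 0.807) and oxidative phosphorylation (0.798). They turned without Cre-negative 3 or Cre-positive 3 for handling genes (0.800 and 0.684) and proliferation (0.554 and 0.902), and without Cre-negative 3 for absorptive enterocyte (0.581). With each library left out, the adjusted p ran from 2.53e-07 to 0.902 for absorptive enterocyte, from 1.84e-04 to 0.800 for handling genes and from 1.86e-05 to 0.902 for proliferation. With the group reduced to Cre-positive 3 they turned for B cell genes (0.546) and oxidative phosphorylation (0.893).

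Over the list alone, the count of 14 alpha-defensins became 5 with a minimum fold of 1.5, 8 with the group reduced to Cre-positive 3 and 7 with exact symbols, where 12 members were tested, and stayed between 10 and 19 elsewhere. The count of 5 clock genes became 3 with a pseudocount of 5, 2 without a filter, 2 with median-of-ratios scaling, 2 with quantile normalization, 11 with array weights, 0 with the minimum fold, 1 with a sex term, 0 with the group reduced to Cre-positive 3, and 1 to 5 with a library left out.

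The log2 fold change of Il17ra stayed between 0.15 and 0.35 except with the group reduced to Cre-positive 3 (-0.0176), and that of Atoh1 between 0.00406 and 0.22. Of 2978 values of 152 single genes, 2917 kept their direction and side of the threshold, 45 came to pass it and 16 turned. As no gene passed in the planned test, no call could be lost. Keeping a side meant only staying short of the threshold, so this tally says little about stability. With array weights S100a8 (0.45), Hspb1 (0.0291), Dnaja1 (0.0721) and Il33 (0.16) turned. Reg1 turned without Cre-negative 3 (-0.26) or Cre-positive 2 (-0.10), Il33 without Cre-negative 3 (0.0490) and Hba-a1 without Cre-positive 1 (0.0288). With each library left out they ran from -0.26 to 0.85, from -0.43 to 0.0490 and from -0.67 to 0.0288. With the group reduced to Cre-positive 3, Lcn2 (0.0723), Btg2 (-0.0879), Cd2 (-0.0930), Clu (-0.47), Ccl21a (-0.27), Madcam1 (-0.48), Cxcl13 (-0.47) and Mfge8 (-0.14) turned. None of these passed in the planned test, and the causes were not tested.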

Other observations

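Except for the median over clock output genes, the tests below were chosen only after the results they bear on were seen. Some genes of lymphoid follicles, named after the B cell values were seen, were high in the same libraries as the B cell genes, and others were not. Cxcl13, the chemokine that draws B cells into follicles, stood at 2.38, 1.53 and 2.13 FPKM in the libraries labelled Cre-negative and at 14.9, 12.1 and 1.16 FPKM in those labelled Cre-positive. Ccr7, the homing receptor of naive lymphocytes, stood at 0.862, 0.830 and 0.930 FPKM against 3.52, 3.41 and 1.01 FPKM, while Chst4, a sulfotransferase of high endothelial venules, stood at 6.16, 10.6 and 6.25 FPKM against 7.17, 8.31 and 8.22 FPKM. Ubd, in the list of follicle-associated epithelium, stood at 9.96, 20.6 and 8.27 FPKM against 6.11, 5.03 and 10.9 FPKM. Glycam1, a product of high endothelial venules, was above 0 in Cre-positive 1 and 2 alone, at 2.53 and 7.21 FPKM.

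Xist and the Y-linked genes put 1 animal labelled Cre-negative and 2 labelled Cre-positive in the female class. Across the 6 libraries, the means of the absorptive enterocyte and proliferation lists were inversely related (Spearman's rho = -0.943, exact permutation p = 0.0167; Pearson's r = -0.946, exact permutation p = 0.00417; r = -0.978 without the 2 libraries farthest from the median; 1 relation computed).

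The 10 ways to split 6 samples into 3 and 3 cannot give a share under 0.05. The real split gave 0 genes past the threshold, as many as or fewer than all 10 splits, and the highest of the others gave 7. For gene lists the real split gave 24 and the highest other 19, for alpha-defensins over the list alone 14 and 7, and for clock genes over the list alone 5 and 2, each matched by 1 split, the real one. The split by sex gave the 7 genes. At an unadjusted p under 0.05, the split of Cre-negative 1, Cre-positive 2 and Cre-positive 3 from the rest gave 2083 genes against 459 in the real one. This points to a structure of the samples other than their groups. The same 3 libraries had the lowest absorptive enterocyte means (-0.23, -0.16 and -0.37, against 0.10 to 0.34 in the rest). They also had the highest proliferation means (0.19, 0.15 and 0.32, against -0.45 to 0.04).

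The alpha-defensins went both ways between the groups, where fewer Paneth cells alone would raise none. Of 26 rows, 4 were higher in all 3 libraries labelled Cre-positive, where chance gives 1.3, although single copies are uncertain. That count comes from the same rows as the pattern, so it adds no further evidence. Rows that share reads are also not separate chances. For the lower alpha-defensins, the median of 15 other Paneth genes (-0.28, SD 0.30, lowest -0.55) lay 0.70 above that of all 26 rows (-0.98). The bound for this gap was the SD of 1.73 of the 26 rows. The rows that rose widened it, so the test could hardly come out against fewer Paneth cells. The 19 rows below 0 (median -1.09, SD 0.46) lay 0.81 lower than the other Paneth genes, but were chosen by their sign. Fewer Paneth cells stay open for the lower ones, as neither gap decides. Reads that only moved between copies would leave the summed family unchanged. It differed by -0.71 on the log2 scale of the group means (exact two-sided permutation p = 0.2). This test cannot go below 0.1 for 3 against 3 animals, so it does not show an equal sum. Defa24 alone made up 18901 of 42354 FPKM in the Cre-negative mean and 13909 of 25904 FPKM in the Cre-positive mean. The sum therefore says little about low copies, and shared reads stay open as part of the difference. A strain haplotype carried with the genotype could also differ between littermates. Genes within 5 Mb of the cluster, defensins left out, showed no excess at an unadjusted p under 0.05 (1 of 45, one-sided Fisher exact p = 0.795). Chromosome 8, with those genes but without the tested alpha-defensins, held 33 of 674 (4.90%, against 3.38% on the other chromosomes). The one-sided Fisher exact p for chromosome 8 was 0.0276, or 0.552 adjusted over the chromosomes. The share on chromosome 8 was 1.45 times that of the other chromosomes in the real split and at most 1.38 times in the other splits. Among genes named above, Ocel1 (from 71371298, higher), Rfxank (70130794), B3gnt3 (71690756) and Asah1 (41340197, all 3 lower) lie on chromosome 8, while others lie elsewhere. None of these values excludes a haplotype limited to the cluster or one that reaches other parts of chromosome 8. Copy sharing and a haplotype cannot be told apart without reads, and an effect of the genotype stays open, untested.

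The high B cell genes in Cre-positive 1 and 2 may come from a lymphoid follicle in those tissue pieces. Lists of follicle stroma, follicle-associated epithelium and naive T cell genes had a median log2 fold change of 0.34 over 21 tested members, just above the bound of 0.3 set for it, with 19 estimates above 0. By list the medians were 0.80, 0.12 and 0.34 (camera p with an estimated correlation 0.166, 0.804 and 0.153), so the epithelium over follicles moved least (its list mean in Cre-positive 2, -0.03, lay inside the range of the Cre-negative libraries), and 17 of the 21 genes also had a mean of at least 1 FPKM in the libraries labelled Cre-negative, while 7 stood in the fixed lists. An effect of the genotype in every animal would raise all 3 libraries, but the B cell list mean of Cre-positive 3 was -0.65 against the mean of all libraries, inside the range of the Cre-negative libraries (-0.83 to -0.52). As this rests on 1 library, an effect in part of the animals stays open.

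The clock genes could differ because the groups were sampled at different clock phases, a hypothesis for which the labels give no collection times. A list of 8 clock output genes outside the fixed list, among them Usp2 (0.43) and Por (0.20), was named before its values were seen, with a median above 0.2 set as the mark for a shifted phase and 0 or lower against it. Its median log2 fold change was 0.19, with all 8 estimates above 0, which falls just short of the mark (camera p with an estimated correlation 0.0360). Of the 14 clock genes, 7 had all 3 values of the libraries labelled Cre-positive on 1 side of the others, where chance gives 10% of genes. Collection time and an effect of the genotype on clock genes cannot be told apart here.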
